A study of Streptococcus pneumoniae R6 with 6 samples.

How the data were processed

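RNA sequencing libraries were prepared from exponentially growing Streptococcus pneumoniae R6, a laboratory strain of the pneumococcus without a capsule, at 0, 5 and 15 min after seconeolitsine was added at 8 µM (0.5 times the minimal inhibitory concentration). Per the labels' protocols, ribosomal RNA was depleted, the RNA was fragmented chemically, cDNA was made with random primers and tagged at both ends, and the libraries were amplified by 15 PCR cycles and sequenced as single reads of 75 bases. The 6 libraries were grouped by the time in their titles, with 2 replicates per time. The series design calls the replicates independent, without saying whether they came from separate cultures, so p-values measure the spread between these samples.

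The authors deposited 1 table per library with the raw count of reads for each locus tag of the R6 annotation, not normalized. Bowtie and edgeR are named in the submitters' processing notes without a version or a role. The genome build, the counting program, its use of strand and its handling of reads that map to several places are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense transcripts can therefore share reads in these counts. Each of the tables has 4 empty lines, which were not used. The tables hold 2038 locus tags and pair none of them with a gene name. The gene table that was used (assembly ASM5650109v1 of strain D39) contained 0 of the 2038 tags. For this reason no gene is named, and only 4 locus tags are printed, the 2 that rose most and the 2 that fell most at 5 min, with all 6 libraries, among genes with a mean log2 CPM of at least 4. The 26 functional gene lists fixed beforehand, the topoisomerase genes, GC content, gene length and the distance from the replication origin were not analysed here. Place on the chromosome is given as place in the locus numbering, from 0 to 100% of 2046 numbers, which assumes that the numbering follows the chromosome. It is not a coordinate.

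Library totals ranged from 19985143 to 31753497 counts. Between 10 and 21 genes per library had fewer than 10 counts. Counting error equals the biological variation of 9.4% estimated by edgeR at about 114 counts, and 109 of the tested genes (5.4%) had a mean count below that. Replicate libraries differed by more than sampling noise at each time, with a chi-square statistic over genes of 159.2 (0 min), 43.9 (5 min) and 92.4 (15 min) per degree of freedom. None was therefore treated as a repeat of another. The Pearson correlation of log2 CPM (read counts scaled to the size of each library) between replicates, across genes, was 0.9955, 0.9977 and 0.9974 in the same order.

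The main test was edgeR 4.0.16 (R 4.3.3) in its quasi-likelihood form, on the counts as deposited. Low genes were removed with filterByExpr, which left 2030 genes, and libraries were scaled by the trimmed mean of M-values (TMM). All 6 libraries entered one fit with a mean per time and 3 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method (false discovery rate, FDR) with a threshold of 0.05. "Rose" and "fell" are used for genes past this threshold. Standard errors of log2 fold changes were taken as the fold change over the square root of its F statistic. Log2 CPM values used a prior count of 2. Counts were simulated for the 5 min against 0 min comparison (2030 genes, 200 of them changed, 10 simulations). The fit recovered 84% of genes changed 1.5-fold, 97% of those changed 2-fold and 99.9% of those changed 4-fold, and 5.03% of its calls were false. Rises and falls were drawn with equal chance. The simulation therefore does not test the scaling where most genes change, and 1548 genes were called at 5 min in the data.

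A cluster was a run of genes along the numbering past the threshold in one direction, with at least 5 such genes and never more than 1 other tested gene in between. The number of genes in clusters was compared with 10000 permutations of the gene order. The same counting on 100 shuffled orders of a simulated set of 2000 genes gave p under 0.05 in 4% of them. A far smaller share of its genes was called than in the data, and its neighbours were not linked. It therefore does not test the counting under the conditions of the data. The rule for named genes, fixed before the data were examined, took the 10 highest and 10 lowest log2 fold changes past the threshold at 5 and at 15 min (5 and 5 for 15 against 5 min) with a mean log2 CPM of at least 4 and no overlap between the libraries compared. These genes are described as groups. The alternatives tried were other scalings (DESeq2 size factors, library totals alone), no filter or a minimum of 100 counts, DESeq2 1.42.0, edgeR's exact test, only the 4 libraries compared, the replicate number as a block, leaving out each library or the 10 most counted genes, and other definitions of a cluster. Thinning all libraries to one total and clusters with a minimum change of 2-fold were added after the data had been seen. The comparison of fold changes at 5 and 15 min, which share the 0 min libraries, was set against 100 simulations of unchanged groups. Positional analyses used Python 3.11.15 with NumPy 2.4.6 and numba 0.67.0.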

Results

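Transcription was measured in S. pneumoniae R6 during exponential growth, at 0, 5 and 15 min after addition of seconeolitsine. This compound inhibits DNA topoisomerase I, the enzyme that removes negative supercoils from bacterial DNA, and the series asks how transcription reacts to an increase in negative supercoiling. Each time had 2 libraries. The 0 min libraries held 31753497 and 31074885 counts, the 5 min libraries 24205060 and 19985143, and the 15 min libraries 27963809 and 23824277. The 0 min libraries were the only reference, and no untreated culture sampled at 5 or 15 min was analysed here, so time in culture and treatment were not separated. Biological variation between replicates, as estimated by edgeR, was 9.4%.

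The first comparison asked which genes had changed 5 min after the compound was added. Of 2030 genes, 743 rose and 805 fell. At least 2-fold, 270 genes rose and 377 fell, and at least 4-fold, 68 rose and 78 fell. Among genes with a mean log2 CPM of at least 4, the 10 with the largest rise increased by 3.75 to 4.68 on the log2 scale, and 9 of them lay in clusters of at least 5 neighbours that rose. The 10 with the largest fall, under the same limit, had log2 fold changes from -3.16 to -2.71, and 8 of them lay in clusters of neighbours that fell. Calls were made with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. With library totals alone as the scaling, the median of all genes moved from -0.05 to -0.29 and the split became 553 higher and 990 lower, so directions are relative to the TMM scaling.

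The 2 genes that rose most, among those with a mean log2 CPM of at least 4, were neighbours in the numbering, at 86.4% of its length. The gene spr1767 had 36.6 ± 3.39 CPM at 0 min, 939 ± 124 at 5 min and 586 ± 43.8 at 15 min (SD, n = 2 each). Its log2 fold change was 4.68 (SE 0.14) at 5 min, a 25.7-fold rise, with an adjusted p of 5.94e-07 in edgeR's quasi-likelihood test. The gene spr1768 had 9.64 ± 0.193 CPM at 0 min, 219 ± 29.7 at 5 min and 136 ± 13.8 at 15 min (SD, n = 2 each), a 22.9-fold rise at 5 min. The gene spr0034, at 1.7% of the numbering, fell from 384 ± 5.33 CPM at 0 min to 42.9 ± 4.36 at 5 min and stood at 84.6 ± 6.27 at 15 min (SD, n = 2 each), which was 8.96-fold lower at 5 min with a log2 fold change of -3.16 (SE 0.11). The gene spr1940, at 94.8%, fell from 291 ± 106 CPM at 0 min to 33.0 ± 0.646 at 5 min and stood at 47.4 ± 0.0205 at 15 min (SD, n = 2 each). Its 0 min libraries were far apart, with 7172 and 12567 counts, and its log2 fold change of -3.14 had the larger SE of 0.23. Its place as the second largest fall depends on these libraries, since without 0 min replicate 2 the value was -2.71 and its rank 8, and without 5 min replicate 1 its rank was 3. The gene spr1768 ranked 4 among the rises without 0 min replicate 2 and 3 after thinning of all libraries to one total, and spr0034 ranked 3 among the falls without 0 min replicate 1 or 5 min replicate 2. At 15 min all 4 genes were still past the threshold, with log2 fold changes of 4.0, 3.83, -2.19 and -2.62.

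The second comparison set 15 min against the same 0 min libraries. By then 696 genes were higher and 768 lower, 198 and 282 of them at least 2-fold and 39 and 31 at least 4-fold (edgeR's quasi-likelihood test). Among genes with a mean log2 CPM of at least 4, the 10 with the largest rise had log2 fold changes of 2.84 to 4.0, and 9 of them were also among the 10 with the largest rise at 5 min. The 10 with the largest fall, under the same limit, had log2 fold changes from -2.90 to -2.37, and 6 of them were also among the 10 at 5 min. All 20 of these genes had changed in the same direction at 5 min.

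The changes at the 2 times largely involved the same genes. At both 5 and 15 min 620 genes were higher, where independent lists would share 254.7, and 675 were lower, where independent lists would share 304.6. Across genes, which are not independent replicates, the log2 fold changes at the 2 times had a Pearson correlation of 0.940 and a covariance of 0.925. Unchanged groups simulated against the same 0 min libraries gave a mean correlation of 0.482 and a mean covariance of 0.0118. The direction was the same for 88.4% of genes, against 66.5% in the simulations. The 0 min libraries could not be split into parts of at least 2, so part of the excess in shared calls may come from the shared libraries.

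**Figure D1:**
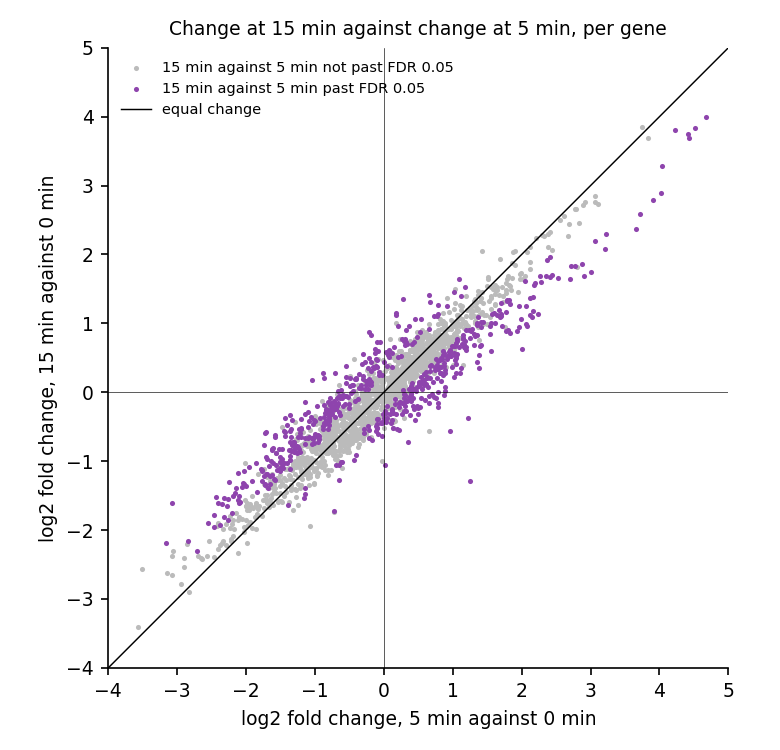
Log2 fold change of each of 2030 genes at 15 min against 0 min (vertical axis) and at 5 min against 0 min (horizontal axis); purple points passed the test of 15 min against 5 min and the line marks equal change. The points follow the line with a correlation of 0.940, and the purple points at large changes lie mostly on the side of a smaller change at 15 min.

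The third comparison, 15 min against 5 min, asked whether the early changes went on or went back. Of 2030 genes, 297 were higher and 276 lower at 15 min than at 5 min, 12 and 23 of them at least 2-fold (edgeR's quasi-likelihood test). Of the genes that had changed at 5 min, 448 moved back, that is, against their 5 min change, 222 after a rise and 226 after a fall. At 15 min 311 of them were still past the threshold in the same direction and 129 were not past it. The other 8 were past it in the opposite direction. Among the genes changed at 5 min, 41 moved further in the same direction. The 5 min libraries enter both comparisons with opposite sign, so their noise alone favours a move back. Log2 fold changes of these 2 comparisons correlated at -0.602, against a mean of -0.517 in the simulated unchanged groups. The covariance was -0.253, against a mean of -0.0129. Among the 647 genes changed at least 2-fold at 5 min, 251 moved back and 8 moved further, and a median of 79.3% of the log2 change was left at 15 min (quartiles 65.0 and 92.4%). Of the 4 genes above, spr1767 and spr1768 moved back by -0.68 and -0.69 on the log2 scale and spr0034 by 0.98, whereas spr1940, with 0.52 (SE 0.22), did not pass the threshold (adjusted p = 0.111, edgeR's quasi-likelihood test). A late change was one not past the threshold at 5 min and past it at 15 min against both earlier times, in the same direction. It was found for 38 genes that rose and 33 that fell. With only the 5 and 15 min libraries in the fit, 712 genes passed in this comparison in place of 573. Leaving out 1 of these 4 libraries leaves its time with 1 sample, which by itself can lower the number of calls. The 573 calls became fewer whichever of them was left out. They became 180 without 5 min replicate 1, 252 without 5 min replicate 2, 254 without 15 min replicate 1 and 232 without 15 min replicate 2. The genes moving back numbered 156, 206, 219 and 192 in the same order, and the late genes 17, 38, 25 and 24. With library totals alone, the split became 608 higher and 141 lower, and that of at least 2-fold turned round to 33 higher and 7 lower, with a median of 0.18 over all genes in place of 0.02.

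The series title refers to clusters of genes that react to DNA topology, so changes were compared along the chromosome. At 5 min, 565 of the genes that rose lay in 56 clusters, and 640 of the genes that fell lay in 66 clusters. Permuted gene orders gave means of 246.8 and 322.9 genes, and none of 10000 reached the observed numbers (permutation p = 1e-04 for both, one-sided, the smallest these permutations can give). The longest clusters held 26 genes that rose and 27 that fell. At 15 min, 508 genes in 51 clusters were higher and 537 in 59 clusters were lower, against permuted means of 197 and 276.6 (permutation p = 1e-04 for both). Where up to 3 genes in between were allowed, most called genes fell into runs in any order and the lower clusters did not differ from permuted orders (permutation p = 0.37 at 5 min and 0.28 at 15 min). Gene order was permuted one gene at a time, so genes transcribed together on one RNA add to the observed numbers and could account for all of them. A planned permutation of blocks of neighbouring genes on the same strand was not made, since no coordinates were available.

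**Figure D2:**
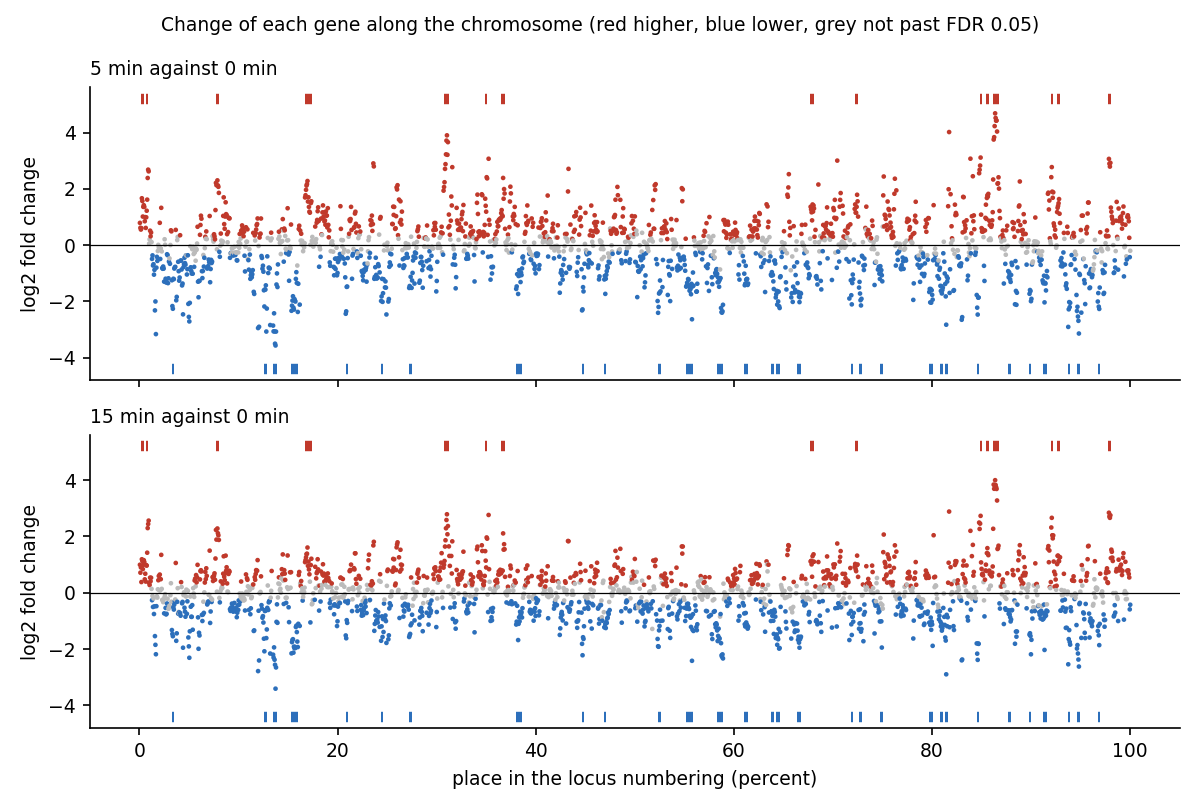
Log2 fold change of each gene (vertical axis) against its place in the locus numbering (horizontal axis, percent) at 5 min (top) and 15 min (bottom); red genes rose, blue genes fell and grey genes did not pass FDR 0.05. Bars at the top and bottom edges mark the 15 higher and 30 lower clusters with a change of at least 2-fold at 5 min.

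A minimum change of 2-fold was a definition chosen after the data had been seen. With it, the 5 min changes formed 15 higher clusters with 113 genes and 30 lower clusters with 219 genes. Permuted orders gave means of 4 and 17.5 genes (permutation p = 1e-04 for both). Genes were again permuted one at a time, so these p-values do not separate the clusters from genes transcribed together on one RNA. The higher cluster with the largest mean change, at 86.1 to 86.8% of the numbering, had 15 genes with log2 fold changes of 1.17 to 4.68. It includes spr1767 and spr1768. Its mean log2 CPM was 5.14 ± 0.12 at 0 min, 8.30 ± 0.14 at 5 min and 7.69 ± 0.06 at 15 min (SD, n = 2 each). The next, at 30.7 to 31.2%, had 11 genes and rose from 3.80 ± 0.09 to 6.58 ± 0.02 before standing at 5.64 ± 0.14 at 15 min (SD, n = 2 each). A run of 5 genes at 84.8 to 84.9% rose from 2.78 ± 0.04 to 5.18 ± 0.12 and stood at 4.94 ± 0.07 at 15 min (SD, n = 2 each).

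The lower cluster with the largest mean change held 10 genes at 13.5 to 13.9% of the numbering, with a mean log2 fold change of -2.55 at 5 min. That rank depends on 0 min replicate 2, without which its mean was -2.07 and that of the run at 93.7 to 93.9% was larger in size, at -2.22. The 0 min libraries of the 10-gene cluster differed, with mean log2 CPM of 4.22 and 5.01. Both lay above the 5 min mean of 2.21 ± 0.02 and the 15 min mean of 2.74 ± 0.12 (SD, n = 2 each). Most members of this cluster lay below the mean log2 CPM of 4 required of named genes. The lowest, at -0.11, had 4 counts in each 5 min library. With a minimum of 100 counts in a time's mean, the cluster still ranked first, at -2.48. A run of 5 genes at 93.7 to 93.9% fell from 7.03 ± 0.10 to 4.74 ± 0.02 and stood at 5.21 ± 0.02 at 15 min (SD, n = 2 each). A run of 8 genes at 94.6 to 94.9%, which includes spr1940, fell from 7.08 ± 0.17 to 5.01 ± 0.09 and stood at 5.49 ± 0.11 (SD, n = 2 each). Its place among the 3 lower clusters with the largest mean change is taken by a run at 84.5 to 84.7% without 0 min replicate 2 (-2.03) or 5 min replicate 1 (-2.06). The clusters with the most members in the lower direction held 15 genes at 55.2 to 55.9%, with a mean log2 fold change of -1.53 at 5 min and -0.90 at 15 min, and 13 genes at 15.3 to 16.0%, with -1.92 and -1.75.

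**Figure D3:**
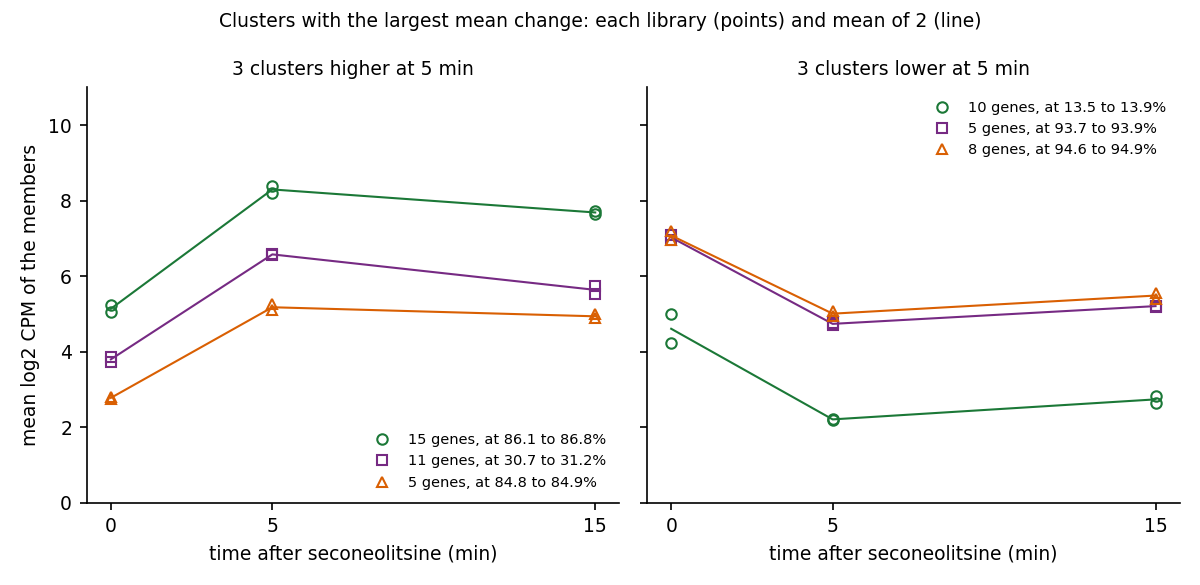
Mean log2 CPM of the members (vertical axis) of the 3 higher (left) and 3 lower (right) clusters with the largest mean change at 5 min, against time after seconeolitsine in minutes (horizontal axis); each point is 1 library and lines join the means of 2. The libraries of each time lie close together except at 0 min in the 10-gene cluster (4.22 and 5.01), which ranks second among the lower clusters without 0 min replicate 2; the 8-gene lower cluster gives way to a run at 84.5 to 84.7% without that library or 5 min replicate 1.

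The clusters kept their direction at 15 min, and differed in how much of the change was left. Of the 113 genes in higher clusters, 111 were also higher at 15 min, and of the 219 genes in lower clusters 217 were also lower. The mean change was smaller at 15 min in 13 of the 15 higher and 29 of the 30 lower clusters. The clusters were chosen for their change at 5 min, which favours a smaller change at 15 min. They were not measured in libraries left out of that choice. Both comparisons share the 0 min libraries, which favours the same direction. In the 11-gene cluster at 30.7 to 31.2%, 10 genes moved back between 5 and 15 min and the mean change between these times was -0.94. All 8 genes of the cluster at 72.2 to 72.5% and 12 of the 15 genes at 55.2 to 55.9% also moved back. In contrast, no gene passed the threshold for moving back in the 7-gene higher cluster at 97.8 to 98.1%, and 2 of its genes moved further. Its mean log2 CPM was 10.48 ± 0.10 at 5 min and 10.48 ± 0.11 at 15 min (SD, n = 2 each). Nor did any gene move back in the 12-gene lower cluster at 58.3 to 58.9%, where 1 gene moved further. Its values were 3.95 ± 0.03 and 3.91 ± 0.14 (SD, n = 2 each). At least 1 gene moved back in 9 of the 15 higher and 24 of the 30 lower clusters. Calls of moving back became fewer when any 1 of the 5 or 15 min libraries was left out, as described above.

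The correlation of log2 fold changes between adjacent genes was 0.711 at 5 min and 0.685 at 15 min, across genes, which are not independent replicates. It was 0.661 for 15 min against 5 min. It fell to 0.276 at a distance of 5 genes and 0.128 at 10 genes in the 5 min comparison. The extremes of 1000 permuted gene orders lay within 0.083 of 0 in that comparison, a range that the observed correlation entered at a distance of 17 genes (0.061) and left again at 46 and 47 genes (0.096 and 0.092). Extremes were taken at distances of 1 and 3 genes only. For 15 min against 5 min they lay within 0.079 of 0. The observed correlation was above them at all 12 distances from 39 to 50 genes, with a maximum of 0.112. Genes were permuted one at a time here, which breaks the link between neighbours, so this range is no test at long distances. Against permuted blocks of 20 genes, the mean correlation over 21 to 50 genes had a two-sided permutation p of 0.064 at 5 min. For 15 min against 5 min the same test gave 0.0011.

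**Figure D4:**
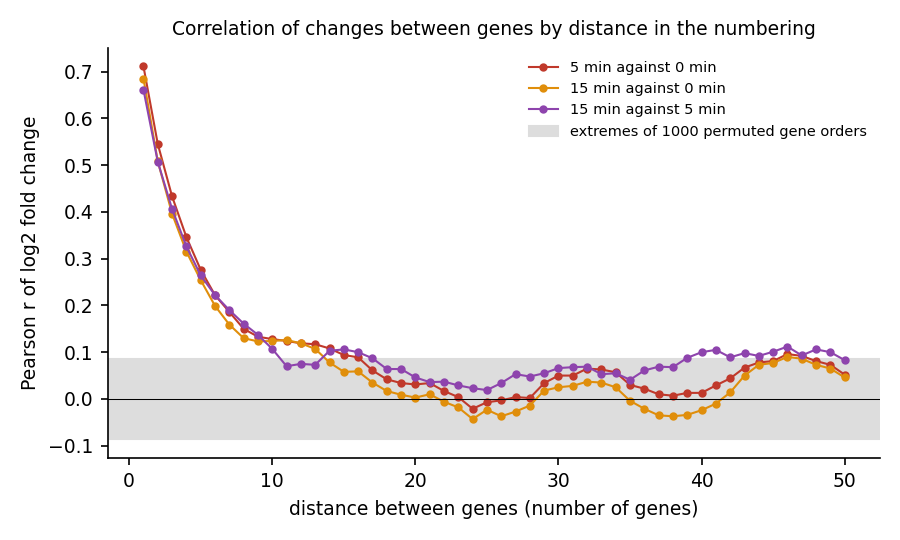
Pearson correlation of log2 fold changes (vertical axis) between genes by distance in the numbering (horizontal axis, number of genes) for the 3 comparisons. The grey band lies within 0.086 of 0, the widest extremes over the 3 comparisons in 1000 permuted gene orders. These extremes were taken at distances of 1 and 3 genes. The correlation falls from 0.711, 0.685 and 0.661 for adjacent genes into the band at 17 genes in the 5 min comparison. For 15 min against 5 min it lies above that comparison's own extreme of 0.079 again from 14 to 17 genes and from 39 to 50 genes. Genes were permuted one at a time, which breaks the link between neighbours, so the band is no test at long distances.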

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

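All tests in this part were chosen after the result was seen, except the test of 15 min against 5 min and the tests of selection and of scaling.

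The effects at 5 and 15 min differed for 573 genes, by the direct test of 15 min against 5 min (edgeR's quasi-likelihood test; 180 to 254 when any one of the 5 or 15 min libraries was left out). Among the genes named individually, the effect differed for spr1767 (log2 change of -0.68 from 5 to 15 min), spr1768 (-0.69) and spr0034 (0.98), each of them towards the 0 min level. The effects of 8 genes were past the threshold in opposite directions at the 2 times, 7 of them higher at 5 min and lower at 15 min, with mean log2 CPM of 7.44 to 12.3.

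The pattern behind these results was that changes at 15 min were smaller than those at 5 min, with an SD of log2 fold changes across genes of 0.907 against 1.085. Selection of genes that were extreme at 5 min by chance would leave no return in other libraries. Genes chosen at 2-fold in one replicate number, however, moved back in the libraries of the other. The medians were 0.318 (higher) and 0.325 (lower) in one direction of the split and 0.359 and 0.303 in the other. The smallest had a 95% bootstrap interval over genes of 0.247 to 0.339. Each median rests on 1 library at 5 min and 1 at 15 min, so this interval leaves out the spread between libraries. A wrong scaling of the 5 min libraries would move risen and fallen genes the same way, whereas the medians of both sets moved back, that of the fallen by 0.325 and 0.303 in the 2 directions of the split. Unequal depth does not account for it either, since the ratio of the SDs was 0.837 after all libraries had been thinned to one total and 0.835 before. A partial return of transcription towards its starting state is a hypothesis that may explain the pattern (medians of 0.303 to 0.359), and a drift of the culture with time stays open and untested, because no untreated culture was analysed here.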

How the results depend on the processing

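Of the 208 alternative values computed for the counts, correlations and clusters, 187 stayed within 1.5 times the main value and, where a cluster was tested, on the same side of its threshold. These are totals: with library totals alone the genes changed at least 2-fold for 15 min against 5 min were 33 higher and 7 lower, against 12 and 23. All 128 alternative values of the 4 individually named genes stayed past the threshold in the same direction, between 4.44 and 4.81 for spr1767, 4.28 and 4.65 for spr1768, -3.40 and -3.07 for spr0034, and -3.47 and -2.71 for spr1940 at 5 min. The genes changed at 5 min numbered 1510 to 1581 under the other scalings, filters, tests and fits, and those changed at 15 min 1416 to 1510. No called gene passed the threshold in the opposite direction under any of these settings. With library totals alone, 1358 of the 1548 calls at 5 min were kept in the same direction. Genes whose call was lost are not covered by this statement. Leaving out 1 library gave 180 to 702 genes for 15 min against 5 min (573 with all), 156 to 524 genes moving back (448) and 17 to 92 late genes (71). Each low count came from leaving out a 5 or 15 min library, which leaves that time with 1 sample, assumed to vary like the others. A minimum change of 1.5-fold left 284 genes in higher clusters at 5 min, and 223 in higher and 297 in lower clusters at 15 min. A minimum of 2-fold left 113 and 219 genes at 5 min and 70 and 141 at 15 min, all with a permutation p of 1e-04. With 3 genes allowed in between, the lower clusters held 704 genes at 5 min (permutation p = 0.37) and 653 at 15 min (0.28), because permuted orders then also gave means of 697.7 and 642.7. Replicates share numbers across times, but nothing says that a number marks a shared culture. The deviations of same-numbered libraries correlated at -0.06 (0 and 5 min), 0.12 (0 and 15 min) and 0.39 (5 and 15 min), which with 2 numbers does not establish a pairing. With the replicate block, 1581, 1510 and 674 genes passed in the 3 comparisons, and every other summary value stayed within 1.5 times its value without the block. No locus tag could be matched to a gene or a coordinate. For this reason the settings meant for the topoisomerase genes, the gene lists, the distance from the origin, GC content and length were not run. The planned permutation of gene blocks was left out as well. Thinning all libraries to one total kept 98.6% of the calls at 5 min.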

Other observations

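The test of depth, the test of background reads, the test of expression level and the test of regional return were planned before their results were seen; the tests of overlapping neighbours, of short transcription units, of distant genes between 5 and 15 min, of the 0 min level and of randomly assigned changes were chosen after the results they concern had been seen.

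Neighbouring genes changed together, with a correlation of 0.711 at 5 min. Neighbours that share an expression level could give this if change followed that level, but the correlation was 0.675 after the trend on mean log2 CPM had been removed and 0.71 after that on the 0 min level. Reads counted for both of 2 overlapping genes would link adjacent genes only, whereas genes 3 apart still correlated at 0.433, above every one of 1000 permuted orders. Transcription units of up to 20 genes remain a possible explanation for the pattern at 5 min. The mean correlation over distances of 21 to 50 genes was 0.038, which was not past the threshold against permuted blocks of 20 genes (permutation p = 0.064, two-sided, 10000 permutations; 0.014 and p = 0.41 at 15 min).

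To ask whether the return between 5 and 15 min differed between regions of the chromosome, the 5 to 15 min change of each gene was taken after regression on its 5 min change, within each replicate number, and correlated between adjacent genes across the 2 replicates, so that noise of a single library could not produce it. The correlation was 0.533, against at most 0.088 in 1000 permuted orders, and that of the same gene between replicates was 0.812. This is consistent with a return that varies by region (0.533), and for adjacent genes transcription on one RNA would show it as well. Over distances of 21 to 50 genes, the mean correlation of the change from 5 to 15 min was 0.068, beyond what permuted blocks of 20 genes gave (permutation p = 0.0011, two-sided; 0.0033 after Benjamini-Hochberg adjustment over the 3 comparisons), and 0.064 between genes of different replicates (permutation p = 0.0011). The blocks were cut without knowledge of transcription units, so units across a cut were broken up in the permuted orders. Transcription units of up to 20 genes alone are therefore not excluded for this part, which is small, and its origin stays open.

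The 5 min log2 fold change had a Spearman correlation of 0.223 with mean log2 CPM across genes, but that mean contains the 5 and 15 min libraries. Giving the observed changes to genes at random produced a mean correlation of 0.22 (central 95% of 1000 assignments, 0.18 to 0.263), so a value of this size arises without any trend. With the 0 min level the correlation was 0.013, and it was 0.055 and -0.027 with level and change taken from different replicates. The tests of depth (0.227 after thinning to one total) and of background reads (0.243 among the 1015 genes above the median count) used the same mean and decide nothing. No trend with expression level is therefore reported.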
